A study of Mus musculus with 6 samples.

How the data were processed

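RNA was measured in 6 libraries of sorted fibroblasts, 3 of Ly6C+ and 3 of Ly6C− PDPN-positive cells that were negative for Ter119, CD45 and EpCAM, from 4T1 tumours in BALB/c mice. The labels name the injected cells once as a GFP line and once as a luciferase line. The deposited table holds signal values, which are normalised counts: the authors divided the count of each gene by 1 size factor per library. Per the submitters' processing notes the upstream tools were bcl2fastq, STAR 2.4.2a and HTSeq on mm10. The tool for the size factors, the annotation, the handling of strands and of molecular tags, and any gene filter were not given in the sources used here.

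Every value of a library was a whole multiple of 1 step (100% of values within a tolerance of 0.001), so the step was taken as the value of 1 read and whole reads were recovered. The step was 0.610 to 1.31, and the deposited size factors were 1.13 to 1.18 times those recomputed by median of ratios. A floor of 3 reads over the group stood in for groups without reads. Ratios on 1 to 3 reads carry an exact 95% counting interval, and intervals and floors cover counting error only. The table has 12235 genes, 72 of them at 0 in all 6 libraries. Coordinates and overlapping genes came from GENCODE M21 for 12044 symbols (98.4%).

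Deposited values were taken to log2 after adding 1, and 9646 genes with a mean deposited value of at least 5 were tested, which held 99.6% of the reads. The main test was limma 3.58.1 (R 4.3.3), with a mean-variance trend in the prior, no block, and Benjamini-Hochberg adjusted p under 0.05. It is a model across all genes and its p-values rest on 3 libraries per group. Gene lists with at least 5 tested members, 24 of 30, were tested with camera at a preset correlation of 0.01, adjusted over the 24 lists, and again with an estimated correlation and with fry. The lists covered sort markers, inflammatory CAFs, contractile genes, fibrillar collagen and matrix, basement membrane, matrix remodelling, TGF-beta response, adventitial fibroblasts, RUNX factors, DNA methylation enzymes, complement, interferon response, MHC class I and II, chemokines and cytokines, cell cycle, hypoxia and glycolysis, immediate early genes, unfolded protein response, oxidative phosphorylation, cytosolic ribosome, and markers of epithelium, macrophages, granulocytes, lymphocytes, endothelium, pericytes and smooth muscle, erythroid cells, adipocytes, and Schwann and muscle cells. Some genes belong to more than 1 list.

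The test, the filter, the lists, the alternatives and the rule for naming genes were set before the data were examined. The rule names, in each direction, the 12 genes with the largest log2 fold change among those past the test with a mean of at least 20 and no overlap between the groups, leaving out predicted genes, pseudogenes and the Ly6c pair. It adds the sort markers, the RUNX genes and, per list, up to 4 members with the smallest p, or up to 8 where a list leads a paragraph. Other members that are named to complete a count of 5 or fewer were chosen after their values were seen.

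The alternatives were a pseudocount of 0.5 or 5, no filter or a mean of at least 20, quantile normalization, recomputed median-of-ratios size factors, each library scaled to its own total, no mean-variance trend, a robust prior, the replicate number as a block, each library left out in turn, edgeR 4.0.16 (quasi-likelihood, TMM or RLE factors, with and without the block) and DESeq2 1.42.0 on recovered reads, and adjusted p thresholds of 0.01 and 0.1. Thinning all libraries to 1176909 reads and a correction for GC content of the last 500 bases of the transcript were added after the data were seen.

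The pipeline was tested on simulated data of the same depth and spread with 200 changed genes among 9646. Of 100 genes changed 2-fold limma called 26% and of 100 changed 4-fold 88%, with 4 false calls of 118. The figures for edgeR were 31% and 92% (8 of 131 calls false) and for DESeq2 34% and 89% (11 of 134). The 118 limma calls compare with 1647 in the real data. With fewer calls the adjustment sets a stricter cut on the unadjusted p, so these shares are not those of the real test. Camera called 0 of 24 lists in simulated data where no list was shifted as a whole. The 200 changed genes were drawn at random without regard to the lists. A list shifted by 1 on the log2 scale had a camera adjusted p of 1.35e-26. Genes were simulated independently, so the 0 lists do not show how often correlation between genes gives false list calls. Tables and figures used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.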

Results

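Gene expression was measured in podoplanin-positive cancer-associated fibroblasts (pCAFs) sorted from mouse breast tumours. The tumours grew from 4T1 cells, a mammary carcinoma line of BALB/c origin, injected as 100000 cells into the mammary fat pad of 8-week-old BALB/c females. The sort excluded cells that carried Ter119, CD45 or EpCAM, markers of erythroid, immune and epithelial cells, and then parted the PDPN-positive cells by the surface protein Ly6C. There were 3 libraries of Ly6C+ and 3 of Ly6C− pCAFs, each a 3′ end mRNA library. The table held 12235 genes. The Ly6C+ libraries held 2818269, 2283453 and 2150531 reads on these genes, and the Ly6C− libraries 1467440, 1721480 and 1176909. Values below are normalised counts, given as mean ± SD over the 3 libraries of a group. Folds are ratios of group means, and log2 fold changes (Ly6C+ minus Ly6C−) come from limma on log2(value + 1), which understates the change of genes with low values.

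The sort markers followed the labels. Ly6c1 (chromosome 15, 75044018 to 75048830, minus strand, protein coding, mm10) stood at 3102 ± 767 in Ly6C+ and 77.2 ± 11.5 in Ly6C− pCAFs, 40.2-fold higher. Its paralog Ly6c2 was near the floor, at 31.7, 10.5 and 2.32 in the Ly6C+ libraries against 1.97, 0 and 0 (69 and 2 reads, ratio 22.6, counting interval 6.37 to 201). Its call (limma adjusted p = 0.0357) ended without Ly6C+ replicate 1, Ly6C+ replicate 2, Ly6C− replicate 2 or Ly6C− replicate 3 (adjusted p = 0.202, 0.119, 0.107 and 0.0589). Reads of this pair of near-identical genes may be divided uncertainly between them. Pdpn, the marker that both gates required, was 2.19-fold higher in Ly6C+ pCAFs (209 ± 24.1 against 95.4 ± 41.3; limma adjusted p = 0.00915). Epcam stayed at or below 2.95 and Ptprc, which encodes CD45, at or below 4.88 in every library. As Ly6C was the sorting criterion, the Ly6c1 difference checks the labels and is no finding.

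The comparison of the 2 groups asks how the transcriptome of PDPN-positive fibroblasts differs with surface Ly6C. Of 9646 genes tested, 1647 differed at an adjusted p under 0.05 (limma), 908 of them higher and 739 lower in Ly6C+ pCAFs. At least 2-fold changes made up 1228 of these, 689 higher and 539 lower. With each library scaled to its own total instead, 1947 genes passed, 37.4% of them higher against 55.1% here, because that scaling moved the median log2 fold change of all genes by −0.18. The first principal component held 61.5% of the variance and separated the groups, and Pearson's r of log2 values across genes was 0.957 to 0.968 among Ly6C+, 0.916 to 0.954 among Ly6C− and 0.850 to 0.877 between groups. The values of the 2 groups did not overlap for 33.1% of the tested genes, where chance gives 10%.

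**Figure D1:**
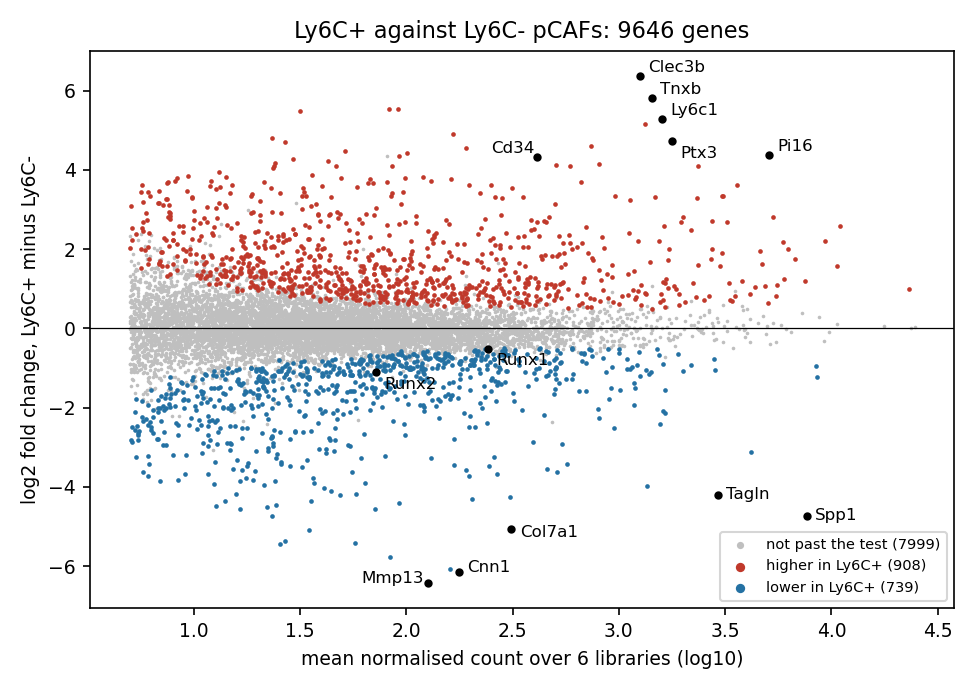
Log2 fold change (Ly6C+ minus Ly6C−) of each of 9646 genes against the log10 of its mean normalised count over 6 libraries. Red points are the 908 genes higher and blue points the 739 genes lower in Ly6C+ pCAFs at a limma adjusted p under 0.05, grey points the rest, and black points the genes named on the plot, of which Runx1 did not pass.

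The 12 genes with the largest increases among those with a mean of at least 20 are given here. Clec3b, which encodes the plasminogen-binding protein tetranectin, stood at 2473 ± 1159 in Ly6C+ and 29.8 ± 14.8 in Ly6C− pCAFs, 82.9-fold higher (log2 fold change 6.37, SE 0.42; limma adjusted p = 2.60e-06). It lies on chromosome 9, 123150946 to 123157432, plus strand. Tnxb, the gene of the matrix glycoprotein tenascin-X, was 57.2-fold higher (2802 ± 827 against 49.0 ± 16.1). Ptx3, a soluble pattern-recognition molecule, was 26.8-fold higher (means 3436 and 128), and Sfrp4, a secreted Wnt antagonist, 35.8-fold higher (2594 ± 963 against 72.5 ± 26.2). Prg4, which encodes lubricin, was 24.6-fold, the fibulin gene Efemp1 24.0-fold and Pamr1 34.4-fold higher. Wfikkn2, a secreted protease-inhibitor domain protein that binds GDF8 and GDF11, and the scavenger receptor gene Scara5 had Ly6C− means of only 2.43 and 3.47, and log2 fold changes of 5.55 and 5.54. The kinase gene Syk had a log2 fold change of 4.70 (52.5 ± 16.1 against 1.22 ± 1.07). Efhd1 rested on 3 reads in the Ly6C− group, which gives a ratio of 54.1 with a 95% counting interval of 15.9 to 230. Mrgprg had no read in that group and was at least 62.4-fold higher in Ly6C+ pCAFs, taking 3 reads over the group as the floor, with uneven values of 142, 28.6 and 20.1. All 12 passed the test in each of 22 alternative settings.

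The 12 genes with the largest decreases included contractile, protease and matrix genes. Mmp13, the gene of collagenase 3, stood at 1.42 ± 0.760 in Ly6C+ and 252 ± 223 in Ly6C− pCAFs (log2 fold change −6.41, SE 0.51; limma adjusted p = 9.18e-06). It lies on chromosome 9, 7272514 to 7283331, plus strand, and its 3 Ly6C− values were 126, 121 and 510. Mmp10, stromelysin 2, was 54.0-fold higher in Ly6C− pCAFs on 6 Ly6C+ reads, a ratio that ran from 35.97 without Ly6C+ replicate 3 to 182 without Ly6C+ replicate 1. Spp1, which encodes osteopontin, was among the most abundant genes of Ly6C− pCAFs at 14758 ± 2809 against 549 ± 87.6, a 26.9-fold difference, and Col7a1, the anchoring-fibril collagen, was 34.6-fold higher there (607 ± 149 against 17.5 ± 5.66). The smooth-muscle calponin gene Cnn1 (350.1 ± 61.7 against 4.35 ± 2.76) and the enteric actin gene Actg2 (318 ± 40.1 against 4.84 ± 3.79) were 80.5-fold and 65.6-fold higher in Ly6C− pCAFs, or 127-fold and 101-fold without Ly6C+ replicate 2. Nes, the intermediate filament gene nestin, was 26.3-fold and Prr9 74.1-fold higher in Ly6C− pCAFs. Acta1 rested on 3 reads in Ly6C+ pCAFs (ratio 65.2, interval 22.7 to 333) and Slit1, an axon-guidance ligand, on 1 read (ratio 249, interval 39.0 to 8779). The Acta1 ratio was 43.5 without Ly6C+ replicate 3 and 151 without Ly6C+ replicate 2. The granzyme genes Gzme (113 ± 47.5 against 1.58 ± 0.845) and Gzmd (53.7 ± 26.1 against 1 read, ratio 214, counting interval 40.1 to 9007) are near-identical neighbours on chromosome 14, so their separate values are uncertain. All 12 passed in each of 22 alternative settings.

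**Figure D2:**
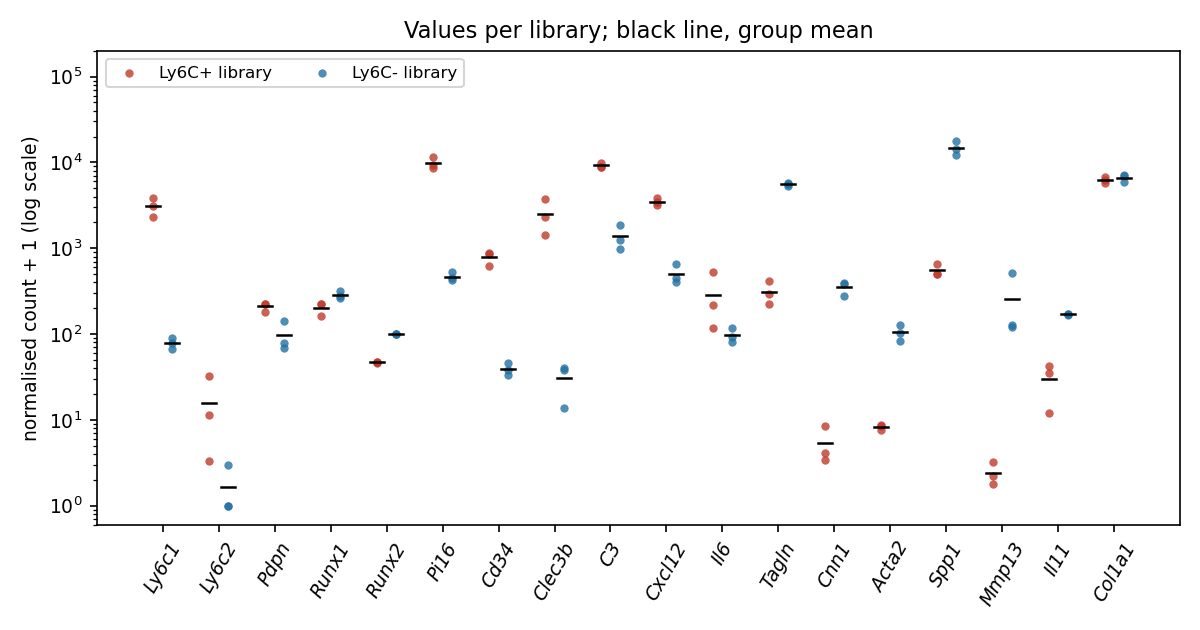
Normalised count plus 1 of 18 genes in each of the 6 libraries, on a log scale. Red points are Ly6C+ and blue points Ly6C− libraries, with a black line at each group mean; the points of the groups do not overlap for 17 of the genes, Col1a1 being the exception.

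Markers of adventitial, or universal, fibroblasts were higher in Ly6C+ pCAFs. Of 19 tested genes of this list, 16 rose, 1 fell and 2 did not pass (17 and 1 adjusted over the list alone), with a median log2 fold change of 3.06 (camera adjusted p = 3.94e-16; adjusted p = 0.0849 with an estimated correlation). Pi16, a marker of perivascular adventitial fibroblasts, reached 9740.0 ± 1566 in Ly6C+ against 467 ± 51.2 in Ly6C− pCAFs, 20.9-fold higher, and Cd34 784 ± 142 against 38.2 ± 6.08, 20.5-fold higher. Ackr3, a scavenging receptor for CXCL12, was 17.8-fold and the matrix protein gene Dpt (dermatopontin) 17.2-fold higher. The semaphorin gene Sema3c was 20.3-fold higher. The member that fell was Col15a1, a basement membrane collagen, 2.94-fold higher in Ly6C− pCAFs (1512 ± 111 against 514 ± 50.5).

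Genes that mark inflammatory CAFs were also higher in Ly6C+ pCAFs. Of 20 tested, 15 rose, 1 fell and 4 did not pass (16 and 3 adjusted over the list alone), with a median log2 fold change of 1.63 (camera adjusted p = 5.70e-11; adjusted p = 0.0604 with an estimated correlation). Cxcl12, a chemokine that retains and attracts leukocytes, stood at 3492 ± 343 against 504 ± 131, 6.93-fold higher. Has1, a hyaluronan synthase, was 9.90-fold higher (2685 ± 471 against 271 ± 60.6), and Ly6a, which encodes Sca-1, 6.42-fold higher. The neutrophil and monocyte chemoattractant genes Cxcl1, Ccl2 and Ccl7 were 3.94-fold, 4.03-fold and 4.03-fold higher. Il6, chosen after its values were seen, stood at 215, 117 and 527 in Ly6C+ and 79.7, 116 and 91.8 in Ly6C− libraries and did not pass (limma adjusted p = 0.0572). It passed without Ly6C+ replicate 2 (log2 fold change 1.82; adjusted p = 0.00601) and in edgeR (adjusted p = 0.0265), over a range of 0.00601 to 0.142 in all alternatives. The member that fell was the IL-6 family cytokine gene Il11, also named after its values were seen, at 28.8 ± 15.8 in Ly6C+ and 168 ± 3.33 in Ly6C− pCAFs. Dpt and Ly6a belong to this list and to the adventitial list.

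Complement genes moved the same way, 9 of 11 rising and none falling (9 and 1 adjusted over the list alone), with a median log2 fold change of 2.15 (camera adjusted p = 1.57e-09; adjusted p = 0.0604 with an estimated correlation). The central component gene C3 stood at 9244 ± 593 in Ly6C+ and 1369 ± 465 in Ly6C− pCAFs, 6.75-fold higher, C4b was 6.48-fold higher, factor B (Cfb) 3.72-fold and C1s1 4.69-fold higher. The 9 also held regulators: Cd55, which speeds the decay of complement convertases, was 21.2-fold higher (45.9 ± 3.42 against 2.16 ± 2.00, on 6 Ly6C− reads), or 14.2-fold without Ly6C− replicate 1 and 35.98-fold without Ly6C− replicate 3. Among 26 secreted chemokine and cytokine genes, 13 rose, 5 fell and 8 did not pass (14 and 7 adjusted over the list alone), with a median of 0.84 (camera adjusted p = 0.00319; adjusted p = 0.260 with an estimated correlation). This list shares Cxcl1, Cxcl2, Cxcl5, Cxcl12, Cxcl14, Ccl2, Ccl7, Ccl11, Il6, Il11, Il33 and Lif with the inflammatory CAF list, so the results of these lists are not independent. Beside the chemokines above, Il33, Cxcl5 and Cxcl13, which attracts B cells, rose. Those that fell were Il11, the angiogenic factor gene Vegfa (2.96-fold higher in Ly6C− pCAFs), Cx3cl1 and the interferon-inducible Cxcl9 and Cxcl10, of which Il11, Cx3cl1, Cxcl9 and Cxcl10 were chosen after their values were seen. The call of Cxcl9 ended without Ly6C+ replicate 3 (adjusted p = 0.0535) or Ly6C− replicates 1 or 2 (0.0782 and 0.0999). That of Cxcl10 ended without Ly6C+ replicates 1 or 3 (0.108 and 0.141) or Ly6C− replicates 1 or 3 (0.112 and 0.0639), and that of Cx3cl1 without Ly6C+ replicates 1 or 2 (0.0746 and 0.0619) or Ly6C− replicate 2 (0.0909).

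Contractile genes of the myofibroblast programme were lower in Ly6C+ pCAFs. Of 19 tested, 15 fell, none rose and 4 did not pass (15 lower adjusted over the list alone), with a median log2 fold change of −2.08 (camera adjusted p = 2.75e-16; adjusted p = 0.0604 with an estimated correlation). Tagln, an actin-binding protein of smooth muscle, stood at 309 ± 94.9 in Ly6C+ and 5536 ± 251 in Ly6C− pCAFs, 17.9-fold higher in the latter. Acta2, which encodes alpha-smooth-muscle actin, was 14.1-fold higher in Ly6C− pCAFs at a low level (103 ± 22.8 against 7.32 ± 0.537). Myl9 and Tpm2, a myosin light chain and a tropomyosin, stood at 941 ± 132 and 847 ± 157 in Ly6C− against 78.2 ± 25.8 and 72.4 ± 22.3 in Ly6C+ pCAFs, and Csrp1 and Tpm1 were 5.28-fold and 4.21-fold higher in Ly6C− pCAFs. Markers of pericytes and smooth muscle cells moved with this group in part: 6 of 9 fell, 1 rose and 2 did not pass (2 higher and 6 lower adjusted over the list alone), with a median of −1.44 (camera adjusted p = 0.00153; adjusted p = 0.0849 with an estimated correlation). Cspg4, which encodes NG2, was 13.7-fold higher in Ly6C− pCAFs (367 ± 39.1 against 26.9 ± 1.80), and Myh11, smooth-muscle myosin, stood at 25.3 ± 4.21 there against 1 read in Ly6C+ pCAFs (ratio 124, counting interval 18.8 to 4332). The pericyte channel gene Kcnj8 was 3.92-fold higher in Ly6C+ pCAFs (means 118 and 30.1).

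Genes of the TGF-beta response were lower in Ly6C+ pCAFs, 7 of 16 falling, 2 rising and 7 not passing (9 lower and 2 higher adjusted over the list alone), with a median of −0.70 (camera adjusted p = 0.00517; adjusted p = 0.270 with an estimated correlation). Lrrc15, a marker of TGF-beta-driven myofibroblasts, stood at 276 ± 56.9 in Ly6C+ and 1624 ± 594 in Ly6C− pCAFs. The ligand genes Tgfb1 and Tgfb3 were 7.10-fold and 3.03-fold, and the cell cycle inhibitor gene Cdkn2b 7.58-fold higher in Ly6C− pCAFs. The members that rose were Itga11 and Ccn1, a collagen-binding integrin and a matricellular protein. Ccn1 (log2 fold change 0.88) did not pass after quantile normalization (0.37; adjusted p = 0.174, the highest of 22 alternatives; lowest 1.40e-05).

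Fibrillar collagen and matrix genes went both ways. Of 22 tested, 5 rose, 4 fell and 13 did not pass (5 higher and 6 lower adjusted over the list alone), and the list did not pass (median −0.02; camera adjusted p = 0.663). Col14a1, a collagen of fibril surfaces, was 12.9-fold higher in Ly6C+ pCAFs (1231 ± 139 against 95.3 ± 24.6) and the small proteoglycan gene Dcn 3.99-fold higher, with Lum, Fbn1 and Col3a1 as the other members that rose. Tnc, tenascin-C, was 8.63-fold higher in Ly6C− pCAFs (7464 ± 1548 against 865 ± 265), where Spp1, Col12a1 and Col6a3 were higher too. Lum lost its call without Ly6C+ replicate 1 (adjusted p = 0.0645). Col6a3, named after its values were seen, lost it without Ly6C+ replicates 1 or 2 or Ly6C− replicate 2 (adjusted p = 0.0926, 0.0549 and 0.0587). Col1a1, chosen after its values were seen, stood at 6237 ± 503 and 6643 ± 643 and did not pass (log2 fold change −0.09; limma adjusted p = 0.794), but it passed after quantile normalization (−0.61; adjusted p = 0.0191), over a range of 0.0191 to 0.944 in all alternatives. Basement membrane genes rose for 6 of 12, fell for 1 (Col15a1) and did not pass for 5 (7 and 2 adjusted over the list alone), with a median of 0.53 (camera adjusted p = 0.0184; adjusted p = 0.270 with an estimated correlation). The laminin genes Lama4 and Lama2 were 2.24-fold and 2.36-fold higher in Ly6C+ pCAFs. Without Ly6C+ replicate 3 the call of this list ended (camera adjusted p = 0.0566), as it did in edgeR and DESeq2, with a range of 0.0103 to 0.270 over all alternatives. Matrix-remodelling genes rose for 4 of 20, fell for 7 and did not pass for 9 (10 and 7 adjusted over the list alone). Their median was 0.40 and their mean −0.53, opposite in sign (median 0.17 without Ly6C− replicate 1 and 0.27 without Ly6C+ replicate 3), and the list did not pass (camera adjusted p = 0.712, direction down). It passed in 1 of 24 alternatives, fry (adjusted p = 0.0366, also down), over a range of 0.0366 to 0.951. Mmp9, gelatinase B, was 12.8-fold higher in Ly6C− pCAFs and its inhibitor family member Timp3 3.37-fold higher there. Among the 4 that rose, Adamts1 was 3.49-fold and Timp2, of the same inhibitor family as Timp3, 2.23-fold higher in Ly6C+ pCAFs.

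**Figure D3:**
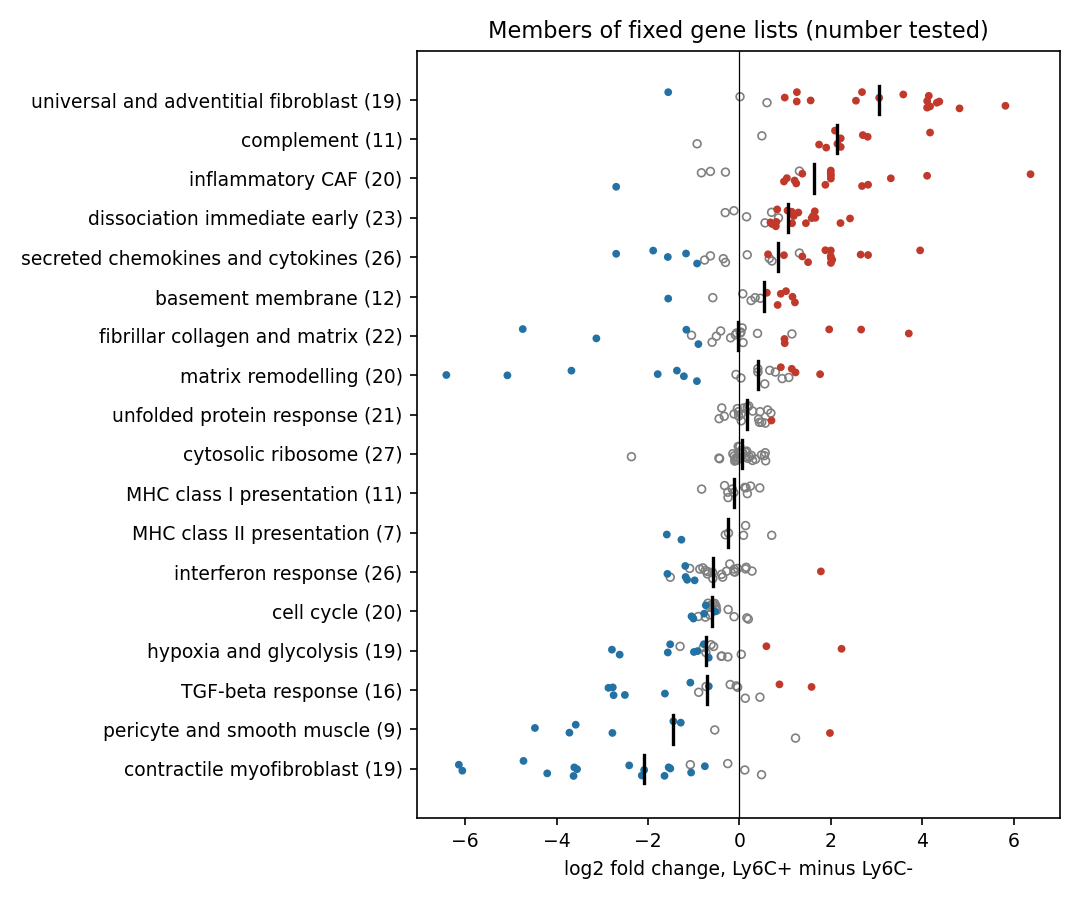
Log2 fold change (Ly6C+ minus Ly6C−) of each tested member of 18 fixed gene lists, the number tested in parentheses. Red and blue points are members higher or lower in Ly6C+ pCAFs at a limma adjusted p under 0.05 over all genes, open circles the rest, and black bars the list medians, from 3.06 for the adventitial list to −2.08 for the contractile list.

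Immediate early and stress genes, which tissue dissociation is known to induce, were higher in Ly6C+ pCAFs. Of 23 tested, 17 rose, none fell and 6 did not pass (19 higher adjusted over the list alone), with a median of 1.05 (camera adjusted p = 4.91e-12; adjusted p = 0.0604 with an estimated correlation). The transcription factor genes Klf4 and Atf3 were 5.35-fold (1888 ± 77.7 against 353 ± 38.8) and 4.67-fold higher (2038 ± 352 against 436 ± 38.8). Socs3, a feedback inhibitor of cytokine signalling, was 2.75-fold, Myc 3.11-fold and the mRNA-decay factor gene Zfp36 2.97-fold higher. Hypoxia and glycolysis genes fell for 8 of 19, rose for 2 and did not pass for 9 (10 lower and 2 higher adjusted over the list alone), with a median of −0.73 (camera adjusted p = 0.000256; adjusted p = 0.0849 with an estimated correlation). Egln3, an oxygen-sensing prolyl hydroxylase, was 6.48-fold and Car9, carbonic anhydrase 9, 9.28-fold higher in Ly6C− pCAFs, the latter 5.11-fold without Ly6C− replicate 1. Adm, the vasodilator adrenomedullin, and the hexokinase gene Hk2 were the members that rose, Hk2 being named after its values were seen. The call of Hk2 (adjusted p = 0.0432) ended in 13 of 22 alternatives, among them 5 of the 6 that left out 1 library (0.0928 to 0.128, with Ly6C− replicate 1 as the exception). Cell cycle genes fell for 5 of 20 and rose for none, with 15 not passing (9 lower adjusted over the list alone) and a median of −0.60 (camera adjusted p = 0.000251; adjusted p = 0.362 with an estimated correlation). The mitotic kinase genes Plk1 and Aurka were 2.06-fold and 2.07-fold higher in Ly6C− pCAFs. Ccnb2, Tubb5 and Cdc20 were the others that fell. Without Ly6C− replicate 2 all 5 lost their calls (adjusted p = 0.0519 for Plk1, 0.0874 for Aurka, 0.103 for Ccnb2, 0.114 for Tubb5 and 0.149 for Cdc20). Of the 6 fits with 1 library left out, Plk1 passed in 5, Aurka in 3 (not without Ly6C+ replicates 1 or 2 either; adjusted p = 0.0559 and 0.0739), Ccnb2 in 2 (without Ly6C+ replicate 2 or Ly6C− replicate 1; highest adjusted p = 0.108), and Tubb5 and Cdc20 in 1 each (without Ly6C− replicate 3).

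Interferon-response genes fell for 5 of 26, rose for 1 and did not pass for 20 (the same numbers adjusted over the list alone), with a median of −0.58 (camera adjusted p = 0.00404; adjusted p = 0.476 with an estimated correlation). Isg15, a ubiquitin-like modifier, stood at 283 ± 19.9 in Ly6C+ and 649 ± 103 in Ly6C− pCAFs, and Igtp, Ifit3 and Irgm1 fell as well. Ifi27l2a rose, 3.47-fold higher in Ly6C+ pCAFs. Of the 12 tested genes whose symbols start with Ifi, itself included, 7 rose and 0 fell, against the direction of this list. The others that rose were Ifi202b, Ifi203, Ifi204, Ifi205, Ifi207 and Ifi211, whereas Ifi27, Ifi30, Ifi35, Ifi44 and Ifi47 did not pass. That comparison was made after the results had been seen. Without Ly6C+ replicate 3 the median of the interferon list was −0.34 and its call ended (camera adjusted p = 0.0580, range over all alternatives 0.000661 to 0.476). Ifit3 lost its call without Ly6C+ replicate 1 or Ly6C− replicate 2 (adjusted p = 0.0608 and 0.0618), and Irgm1 without Ly6C+ replicates 1 or 3 (0.122 and 0.146) or Ly6C− replicates 2 or 3 (0.0739 and 0.114). The MHC class II list gave 2 of 7 lower, the class II chain gene H2-Ab1 and Slpi, a protease inhibitor gene with no part in presentation (2 adjusted over the list alone), and did not pass (median −0.24; camera adjusted p = 0.335). Without Ly6C− replicate 3 the list passed (median −1.49; adjusted p = 0.00278; range 0.00278 to 0.783), and without Ly6C− replicate 1 its median was 0.90. H2-Ab1 lost its call without Ly6C+ replicates 1 or 3 (adjusted p = 0.0574 and 0.0587), and Slpi without Ly6C+ replicates 1, 2 or 3 (0.0582, 0.0968 and 0.0608) or Ly6C− replicate 2 (0.0812). In the MHC class I list no member of 11 passed in limma (0 adjusted over the list alone), against 1 at an unadjusted p under 0.05, 0 in edgeR and 1 in DESeq2 (median −0.12, camera adjusted p = 0.712). With 1 library left out the median of this list ran from −0.32 to 0.21. The unfolded protein response list gave 1 higher of 21, Dnajc3 (0 adjusted over the list alone), with camera adjusted p = 0.335. Of 22 oxidative phosphorylation genes 2 were lower, Uqcrc2 and Atp5b (0 adjusted over the list alone), with camera adjusted p = 0.278. With 1 library left out, Dnajc3 passed in 1 of 6 fits, without Ly6C+ replicate 1 (highest adjusted p = 0.128), and Uqcrc2 and Atp5b in 2 of 6, without Ly6C+ replicate 3 or Ly6C− replicate 1 (highest adjusted p = 0.103 and 0.135). Cytosolic ribosome genes gave no call among 27 in limma (0 adjusted over the list alone), against 2 at an unadjusted p under 0.05, 1 in edgeR and 0 in DESeq2 (camera adjusted p = 0.540).

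The series title names RUNX1 and DNA methylation. Runx1 (chromosome 16, 92601466 to 92826149, minus strand, protein coding, mm10) stood at 159, 222 and 222 in the Ly6C+ libraries and at 262, 274 and 315 in the Ly6C− libraries. The 3 Ly6C+ values all lay below the 3 Ly6C− values, but the log2 fold change of −0.51 (SE 0.18) did not pass (limma adjusted p = 0.0901). It passed where each library was scaled to its own total (log2 fold change −0.70; limma adjusted p = 0.0199) but not in 19 of 22 alternatives, the adjusted p over all 22 lying between 0.0199 and 0.274. Runx2, a regulator of osteoblast differentiation, was 2.16-fold higher in Ly6C− pCAFs (99.0 ± 1.16 against 45.8 ± 0.752; log2 fold change −1.10, SE 0.18; limma adjusted p = 0.00146). Cbfb, which encodes the partner subunit of the RUNX proteins, was low and uneven (30.1 ± 15.6 against 29.3 ± 26.8). Over these 3 tested genes of the RUNX list, 1 fell, or 2 adjusted over the list alone. No gene of 10 for DNA methylation enzymes and readers passed in limma (0 adjusted over the list alone), against 2 at an unadjusted p under 0.05 and 0 in edgeR and DESeq2 (median −0.24; camera adjusted p = 0.534). In fry the list did not pass for a shift in 1 direction (adjusted p = 0.148) but passed for change in either direction (0.00238). The latter also passed for other lists without a camera call, such as unfolded protein response (0.0150) and oxidative phosphorylation (0.0204). Dnmt1, the maintenance methyltransferase gene, stood at 48.8 ± 5.23 and 60.1 ± 8.09.

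Markers of other cell types were mostly low. Of 8 epithelial genes tested, 2 fell, 1 rose and 5 did not pass (4 lower and 1 higher adjusted over the list alone), with a median of −1.48 (camera adjusted p = 0.0395; adjusted p = 0.476 with an estimated correlation). Krt14 and Krt19 were higher in Ly6C− pCAFs (for Krt14 30.9 ± 8.62 against 3 reads, ratio 43.4 with a counting interval of 15.0 to 223, and for Krt19 45.2 ± 17.8 against 3.92 ± 0.938), and Lcn2, also an inflammation gene, was 6.51-fold higher in Ly6C+ pCAFs. This list lost its call without Ly6C− replicate 1 (adjusted p = 0.227) and without Ly6C+ replicate 1 (adjusted p = 0.106), and passed in 12 of 23 alternatives, not in edgeR or DESeq2 among others (range 0.00354 to 0.476). With 1 library left out the median of the epithelial list ran from −2.21 to −0.82. Of 8 granulocyte genes none passed in limma (0 adjusted over the list alone), against 4 at an unadjusted p under 0.05, 1 in edgeR and 0 in DESeq2. The list passed (median 2.01, or 2.55 with 4 members without Ly6C− reads set at their bound; camera adjusted p = 0.0290; adjusted p = 0.476 with an estimated correlation), but not without Ly6C+ replicate 1 (median 1.10; adjusted p = 0.202) or without Ly6C− replicate 3 (adjusted p = 0.0511), and it passed in 16 of 23 alternatives, not in edgeR or DESeq2 among others (range 0.000600 to 0.476). S100a9, an abundant neutrophil transcript, stood at 478 in that Ly6C+ library and at 4.51 and 2.32 in the others of its group. Of 9 macrophage genes 1 rose, Lyz2 (1 adjusted over the list alone), with a median of 0.93 (camera adjusted p = 0.0484; adjusted p = 0.627 with an estimated correlation). Its call ended without Ly6C+ replicate 2, Ly6C− replicate 2 or Ly6C− replicate 3 (adjusted p = 0.144, 0.163 and 0.248), and it passed in 11 of 23 alternatives, not in edgeR, DESeq2 or fry among others (range 0.000236 to 0.627). Its median was 0.24 without Ly6C− replicate 3 and 1.65 without Ly6C− replicate 1. The call of Lyz2 ended without Ly6C+ replicate 1 (0.0746) or Ly6C− replicate 2 (0.0570).

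Endothelial markers went both ways, 3 rising, 4 falling and 1 not passing of 8 (3 and 4 adjusted over the list alone), with a median of −1.47 and no call (camera adjusted p = 0.959). Plvap and Ramp2 were 5.81-fold and 6.91-fold higher in Ly6C+ pCAFs, as was Tek on 3 Ly6C− reads (ratio 15.9, counting interval 6.18 to 92.6), whereas Kdr, Flt4, Egfl7 and Esam were higher in Ly6C− pCAFs. The Tek ratio was 10.6 without Ly6C− replicate 1 and 43.4 without Ly6C− replicate 3. With 1 library left out, Kdr and Esam passed in 1 of 6 fits, without Ly6C− replicate 3 (highest adjusted p = 0.112 and 0.159), and Egfl7 in 2 of 6, without that library or Ly6C+ replicate 1 (highest adjusted p = 0.104). Too few members of the remaining lists were tested for a set test. Fabp4 and Lpl, 2 of 3 adipocyte genes, rose (3 adjusted over the list alone), and Ncam1 and Mylpf, 2 of 4 Schwann and muscle genes, fell (2 adjusted over the list alone), Mylpf not without Ly6C− replicate 2 (adjusted p = 0.0703). Cd3e, the single lymphocyte gene tested, rose, alone and over all genes, at 125 ± 38.2 against 16.3 ± 5.05, and annotated genes overlap it on both strands. The sort marker list had 3 of 3 tested genes higher, also adjusted over the list alone. The erythroid list had none in the table.

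Every Ly6C− library was shallower than the Ly6C+ ones; with all libraries thinned to the shallowest total, an alternative added after the data were seen, 1502 genes passed, among them 1426 of the 1647 (86.6%). The labels do not say that the 3 libraries of a group came from separate animals, so the p-values measure the spread between these libraries, which may be technical, and an exact permutation test of 3 against 3 cannot give a two-sided p below 0.1.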

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

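Over the alternatives limma, edgeR and DESeq2 called 959 to 2150 genes, against 1647, and none of the 1647 calls passed with the other sign in any of them. At an adjusted p under 0.01 959 genes passed, since the threshold was stricter. Leaving out 1 library gave 1121 to 1728 genes and 13 to 14 lists. Scaling each library to its own total moved the median of all genes by −0.18 and called 1947 genes, 37.4% of them higher in Ly6C+ pCAFs. With an estimated correlation 0 lists passed, against 7 at an unadjusted p under 0.05, 15 with camera's preset correlation and 13 with fry. The medians were then as before because only the correlation between genes changed: 3.06 (adventitial), 2.15 (complement), 1.63 (inflammatory CAF), 1.05 (immediate early), 0.84 (chemokines), 0.53 (basement membrane), −0.58 (interferon), −0.60 (cell cycle), −0.70 (TGF-beta), −0.73 (hypoxia) and −2.08 (contractile). The basement membrane list did not pass in edgeR, edgeR with RLE factors, edgeR with the block or DESeq2 (median 0.53 in each; adjusted p over all alternatives 0.0103 to 0.270), and the cause was not tested. Its median was 0.50 to 0.62 with 1 library left out, and it did not pass without Ly6C+ replicate 3. The interferon list did not pass in fry (median −0.58; adjusted p = 0.148), and its median was −0.74 to −0.32 with 1 library left out, not passing without Ly6C+ replicate 3. The cause was not tested.

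Runx1 passed with each library scaled to its own total (−0.70), where the scaling itself moved all genes down, and with the replicate block in limma (−0.51; adjusted p = 0.0337) and edgeR (−0.51; adjusted p = 0.0344), within a range of 0.0199 to 0.274. The replicate block raised the calls from 1647 to 2088 in limma and from 1721 to 2113 in edgeR. The labels do not pair the libraries by number. Deviations from the group mean correlated across genes at 0.129, 0.0518 and 0.167 between libraries of the same number, the highest for each library. After GC correction, added later, the values were 0.0621, 0.0550 and 0.101. The trend with GC content ran the same way in both groups for replicate 1 (Spearman's rho 0.165 and 0.210 across genes) and replicate 3 (−0.253 and −0.199). For replicate 2 it ran opposite ways (−0.0629 in the Ly6C+ and 0.0927 in the Ly6C− library). These correlations neither show nor exclude pairs. Of the other values under the alternatives, 5060 kept their side of the threshold, 182 lost and 126 gained the threshold. None changed direction where it passed in the main fit or in the alternative. Values that passed in neither could change sign, as Cbfb did (log2 fold change −0.37 to 1.09).

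Depth limits what low genes can show: 1 read was worth 0.610 to 1.31, so ratios that rest on few reads carry wide intervals.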

Other observations

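Families of genes that share the start of their symbol were compared after the results had been seen, as were the tests on pericytes, smooth muscle, digestion and base composition below. Of 294 families tested with camera, 7 passed at the preset correlation and 0 with an estimated correlation (lowest adjusted p = 0.992). Wnt ligand genes fell for 4 of 8 in Ly6C+ pCAFs (Wnt11, Wnt2b, Wnt4 and Wnt5a; adjusted p = 0.0184). Wnt5a stood at 59.9 ± 6.86 in Ly6C− and 4.62 ± 1.91 in Ly6C+ libraries. Genes of TNF receptors fell for 4 of 10 (Tnfrsf9, Tnfrsf19, Tnfrsf23 and Tnfrsf26; adjusted p = 0.0184), and Tnfrsf9 was 44.9-fold higher in Ly6C− pCAFs. Colony-stimulating factor and receptor genes rose for 5 of 7 (Csf1, Csf2, Csf3, Csf2rb and Csf2rb2; adjusted p = 0.0184), Ccl chemokine genes for 5 of 6 (0.00218), Ifi genes for 7 of 12 (0.0205), and Adamtsl and Abca genes for 3 of 5 and 5 of 7 (both 0.0252). The tested Ccl genes except Ccl27a, and Csf1, Csf2 and Csf3, are also in the chemokine and cytokine list. Ifi211 was 14.2-fold higher in Ly6C+ pCAFs.

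The contractile list was lower in Ly6C+ pCAFs. A difference in depth is argued against: with all libraries thinned to the shallowest its median was −2.03 and it passed. Whether pericytes in the Ly6C− gate added to it cannot be told. Kcnj8 rose in Ly6C+ pCAFs (log2 fold change 1.98) while Cspg4 fell (−3.72), but these values were known when the criterion was set. A rise of Kcnj8 in Ly6C+ cells also does not exclude pericytes in the other gate. Rgs5 was near the floor in both groups (at most 3.86 in Ly6C+ and 5.24 in Ly6C− libraries). Smooth muscle cells cannot be told apart from fibroblasts with a contractile programme: Myh11 stood at 0.457% of Tagln in Ly6C− libraries, too low to carry it at the level set for smooth muscle yet not 0. A difference between fibroblasts with and without Ly6C, the design's own contrast, stays open and was not tested apart from these.

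The immediate early list was higher in Ly6C+ pCAFs. Depth is argued against, the median after thinning being 1.06. A stronger response to tissue digestion in the Ly6C+ libraries stays open and cannot be told apart from a difference in the tumour: the heat-shock members, which digestion also induces, had a median of 0.16, between the bounds set for either outcome. The labels describe 1 digestion protocol for both groups and give no digestion times.

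Ly6C− replicates 1 and 3 lay apart on the second principal component (17.3% of the variance; 38.9 and −43.2). The difference between them followed GC content across genes (Spearman's rho 0.29, genes not being independent), but 96.4% of the distance was left after GC correction, which argues against base composition as the whole cause. No biological explanation was tested.

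The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. Of the 10, only 1, the real split, gave 1647 genes, 1228 genes changed at least 2-fold and 15 lists. The highest of the others were 0 genes in limma (607 at an unadjusted p under 0.05, against 2753), 0 genes and 13 lists, so camera called many lists in other splits too. Every other split put libraries of both groups into each part. The group difference then adds to the spread within the parts and is partly left between them. The counts of genes and lists in those splits therefore do not measure what chance gives.

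Rps2 stood at 2820.1 in Ly6C− replicate 2 and at most 22.6 in the other libraries. S100a8 stood at 179 in Ly6C+ replicate 1 and at most 3.01 elsewhere. H2-Aa stood at 417, 59.5 and 10.5 in the Ly6C− libraries, and Krt18 at 183 and 97.8 in Ly6C− replicates 1 and 2 and at most 27.8 elsewhere.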
